A study of Homo sapiens with 2 samples.

How the data were processed

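RNA was measured by RNA immunoprecipitation sequencing (RIP-seq) in HUH7 cells, an established line of human hepatocellular carcinoma. Per the series title and the sample labels, 1 library was made from RNA recovered with CSTF2 (the IP library) and 1 from input RNA of the same line (the Input library). CSTF2, also called CstF-64, is the RNA-binding subunit of the cleavage stimulation factor, which takes part in forming the 3' ends of mRNAs. Per the labels' protocols, a commercial RIP kit was used, total RNA was extracted with Trizol, and the RNA was fragmented, copied from random hexamers, ligated to adapters, size-selected on magnetic beads, amplified by PCR and sequenced on an Illumina instrument. The protocols do not state that strand was kept, so reads of a gene and of an overlapping or antisense gene are not told apart here. The submitters' processing notes name FastQC 0.12.0 and the human build hg38. The aligner, the counting program and the annotation are not given in the sources used here. A mock immunoprecipitation was not used here.

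Per the file headers, the authors deposited 1 table with an RPKM value (reads scaled to gene length and to library depth) for each of the 2 libraries and a log2 fold change of IP over Input, for 14914 features. The RPKM columns are the measurement used. The deposited log2 fold change was used only to recover read numbers and, for PGK1, as a value of the authors' deposited table. Features are named by symbol only. Of the 14914 names, 12660 matched a symbol of GENCODE v29 (GRCh38) that belongs to 1 gene and 272 matched through a RefSeq synonym, while 1982 had no match and carry no coordinates or biotype. Among the names, 18 read as calendar dates, a form that spreadsheets give to some gene symbols, and were not interpreted. Coordinates are those of GENCODE v29 on GRCh38.

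Reads were recovered from the deposited values. Among features listed at 0 in 1 library, the deposited log2 fold changes of the authors followed the logarithm of whole read numbers plus a small constant, averaging 0.125 reads per library and scaled to library size (0.0632 reads for the IP, 0.187 for the Input), which is the form that edgeR uses. Solving this relation together with the RPKM ratio gave whole reads in both libraries and a whole gene length for 14913 of the 14914 features, with a tolerance of 0.01 reads. The exception was PGK1. The recovered lengths equalled the exon-union length in GENCODE v29 for 11677 features, 90.3% of those matched. The assigned depth came to 3220045 reads for the IP library and 9517885 for the Input library, so the Input was 2.96 times deeper. The reads of the listed features make up 99.8% of each depth. In the library where it was better covered, every feature with recovered reads reached at least 1.05 CPM, so the table appears to hold only features above about 1 CPM in at least 1 library. An exact 0 therefore means no assigned read. It applied to 313 features in the IP and 492 in the Input. Features that overlap on the genome, such as RPL36A and the readthrough RPL36A-HNRNPH2, were each credited with shared reads (1204 and 1240 in the IP), so values of overlapping features are not independent.

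With 1 library per group there is no replicate error. No p-value or SD is given across libraries, and every difference describes these 2 libraries. The main measure was log2((IP + 1)/(Input + 1)) of the RPKM values, with a pseudocount of 1 RPKM that understates the change of low features, for the 9880 features with a mean of at least 1 RPKM. Features at least 2-fold higher or lower on that scale were counted. Ratios of RPKM are given with an exact conditional (Clopper-Pearson) 95% interval from the recovered reads, and shares of reads have a 95% Wilson interval. These intervals cover counting error only. They treat reads as independent, although PCR reads without molecular identifiers are not independent molecules, so they can be too narrow even for that error. The median log2 ratio of all features was 0.17, and list medians are given relative to it.

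Before the data were examined, 26 gene lists, the measure, the filter, the 2-fold threshold, the alternatives and a rule for the genes named were fixed. The fixed design assumed only that the file held values per library, and the intervals were to be added if reads could be recovered. The rule named CSTF2 and PGK1. It added the 12 features with the highest and the 12 with the lowest log2 ratio among those with a mean of at least 5 RPKM, leaving out small RNAs, pseudogenes and features named only by clone. It also named the 2 highest and 2 lowest members of each list. Sex-linked marker genes were left out. Genes named outside the rule were chosen after their values were seen, or serve to check a locus, an overlap or a paralog, and 2 genes that the rule takes from the lists are not reported here. For each list, the median log2 ratio was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression. A list was said to stand apart below percentile 1 or above percentile 99. This percentile describes the 2 libraries and is not a p-value. Alternatives covered the pseudocount, the filter, the scaling between libraries, the set of features and the fold threshold. Others, added after the data were seen, were a minimum of 20 reads, counting intervals beyond 2-fold, lists matched on gene length as well, and lists without CSTF2 or PGK1.

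The computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and matplotlib 3.10.9 drew the plots. They were tested on simulated reads. For libraries drawn from the real reads of each feature, with 200 features changed, the reads of all 14284 simulated features were recovered (100%). The simulated values were made with the same formula and the recovered lengths, so this shows only that the formula can be inverted. In an IP library simulated from the Input, the interval held the true ratio for 96.1% of 8832 features. The 2-fold threshold called 98.0% of 49 features raised 4-fold, 100% of 50 raised 8-fold, 90.2% of 41 lowered to 0.25 and 100% of 41 lowered to 0.125. It called 0.659% of 8651 unchanged features. The changed features all had at least 20 Input reads, so their rates do not cover features with fewer. Only counting noise was simulated, so none of these rates covers variation from PCR or the immunoprecipitation. In the same simulated libraries, 1 of 100 random lists of 30 features stood apart, and all 100 did after a shift of 0.5 on the log2 scale. Real ratios spread more widely, so this rate does not carry over to the real lists. The 35 proteasome genes, for example, lay at -0.45 against all features and did not stand apart (percentile 1.82).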

Results

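The series asks which RNAs in HUH7 cells are bound by CSTF2, and the comparison is between RNA recovered with CSTF2 (IP, 1 library) and the input RNA (Input, 1 library). The IP library held 3220045 assigned reads and the Input 9517885, over 14914 listed features. A feature past the filter had a median of 44 reads in the IP and 116 in the Input. There are no replicates, so the intervals below cover counting error only and no difference has a replicate check.

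The mRNA of CSTF2 itself had the highest log2 ratio among features with a mean of at least 5 RPKM, leaving out small RNAs, pseudogenes and clone names. The gene lies on chromosome X from 100820359 to 100840932 (plus strand, protein-coding, 2187 bp of exon). It had 3429 reads and 487 RPKM in the IP against 145 reads and 6.97 RPKM in the Input, a ratio of 69.9 (95% interval 59.2 to 83.1). By log2 ratio among those features, the next was STRN4, which encodes a striatin family subunit of PP2A phosphatase complexes, at 20.6-fold (19.1 to 22.2). PCNT, which encodes the centrosomal scaffold pericentrin, followed at 18.3-fold (15.6 to 21.7). HSPA9, which encodes the mitochondrial HSP70 chaperone, was 7.83-fold higher (7.39 to 8.30), and PLBD2, a phospholipase B-like lysosomal protein gene, 7.24-fold higher (6.34 to 8.28). The other 7 of the 12 highest features were mitochondrial: MT-ND6, MT-ND5 and the tRNA genes MT-TH, MT-TS2, MT-TE, MT-TL2 and MT-TG. Mitochondrial tRNAs were not counted among the small RNAs left out.

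Among 9880 features with a mean of at least 1 RPKM, 976 (9.88%) were at least 2-fold higher in the IP, 675 (6.83%) at least 2-fold lower and 8229 within 2-fold. The median log2 ratio was 0.17, a ratio of 1.13. With the ratios centred on that median, 684 were higher and 944 lower, so the higher share of these calls went from 59.1% to 42.0%. On the trimmed mean scaling it was 688 higher to 942 lower. Without rescaling, it was 1830 to 1023 and 186 to 295 with pseudocounts of 0.1 and 5 RPKM, and 327 to 407 with a filter of 5 RPKM, so neither the counts nor the split between directions is fixed by these data. Of the 976 higher features, 446 were protein-coding genes, 337 were named only by clone, 93 were pseudogenes and 30 small RNAs. Fewer than 20 reads in total stood behind 343 of them. Of the 675 lower features, 409 were protein-coding and 88 were small RNAs, and 79 had fewer than 20 reads in total. With at least 20 reads, 632 features were higher and 596 lower, so the excess of higher features rests largely on features with few reads. Among all 9880 features, the counting interval of the RPKM ratio, without a pseudocount, lay beyond 2-fold for 668 higher and 284 lower features. These need not all be among the 976 and 675. Across genes, log2 RPKM of the libraries correlated with a Pearson r of 0.847 and a Spearman rho of 0.732, where genes are not independent replicates.

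**Figure D1:**
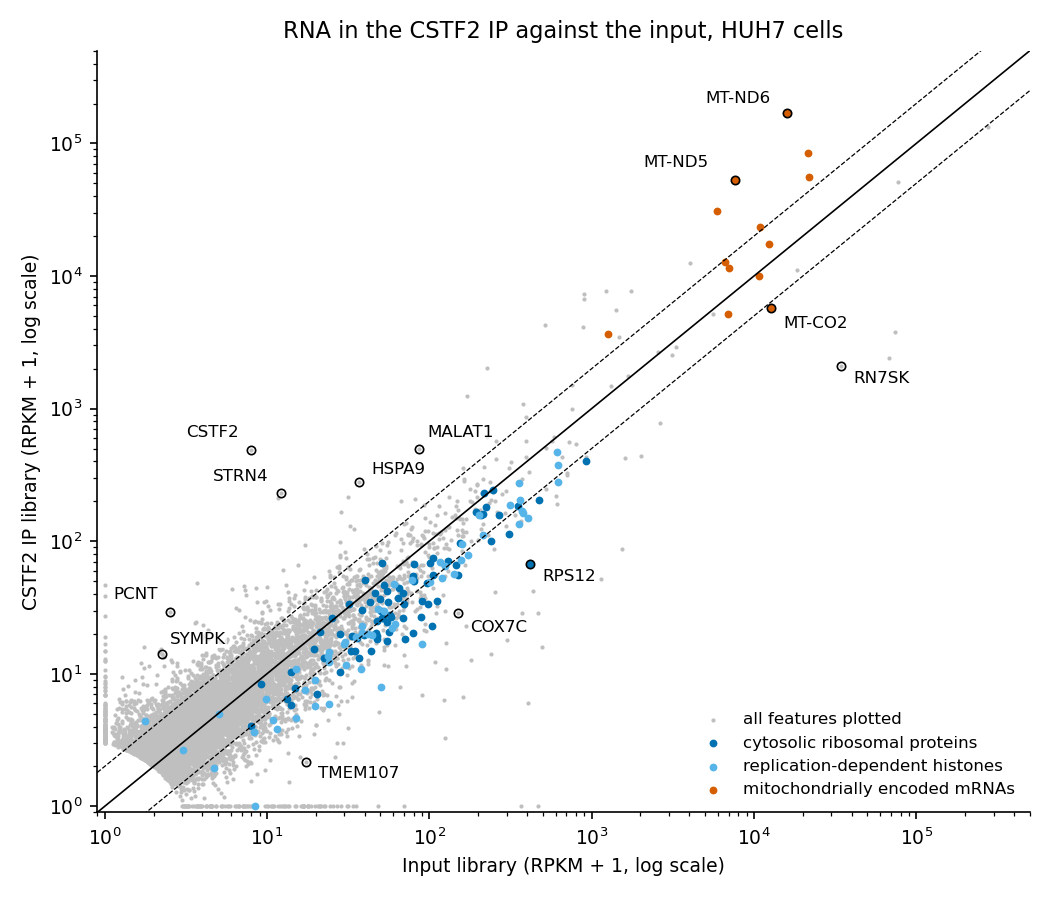
Each point is a feature with a mean of at least 1 RPKM, with its Input RPKM + 1 on the x axis and its IP RPKM + 1 on the y axis (both log scales). The solid line marks equal values and the dashed lines a 2-fold difference. CSTF2 lies at 487 RPKM in the IP against 6.97 in the Input, and most ribosomal protein and histone mRNAs lie below the solid line.

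The classes of RNA took different shares of the reads, and RN7SL1, RN7SL2 and RN7SK are named here outside the naming rule, after their values were seen. Mitochondrial mRNAs made up 35.7% of the IP reads (35.7 to 35.8) and 10.9% of the Input reads (10.8 to 10.9), a ratio of 3.29. The mitochondrial rRNAs took 50.4% of the Input (50.4 to 50.4) and 25.5% of the IP (25.5 to 25.6). The 7SL RNA genes RN7SL1 and RN7SL2, the RNA of the signal recognition particle, took 4.27% of the Input (4.25 to 4.28) and 0.186% of the IP (0.181 to 0.191), which is 22.9 times less. RN7SK, the RNA that holds the transcription elongation factor P-TEFb inactive, took 1.14% of the Input and 0.0688% of the IP (0.0660 to 0.0717), 16.6 times less. Nuclear protein-coding genes had similar shares, 33.7% of the IP and 29.3% of the Input.

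The mitochondrial transcripts did not move as a block. Of the 13 mitochondrially encoded mRNAs, 7 were at least 2-fold higher and 1 was at least 2-fold lower. The list's median lay 0.93 above that of all features, above every matched list (percentile 100). Matching on expression was loose here, because the highest bin of mean expression has no upper limit. MT-ND3, the lowest of the 13 in both libraries, had 3632 RPKM in the IP and 1268 RPKM in the Input. RPS12, a ribosomal protein mRNA, had 66.0 RPKM in the IP and 417 RPKM in the Input. The matched lists had a median log2 ratio of -0.22, against 0.17 for all features. The percentile therefore does not compare these mRNAs with RNAs of like abundance. MT-ND6, the mRNA encoded on the light strand, was 10.6-fold higher (10.5 to 10.7), MT-ND5 6.97-fold (6.92 to 7.01) and MT-ND2, named outside the rule after its value was seen, 5.29-fold (5.24 to 5.34). MT-CO2 was 2.19-fold lower (2.15 to 2.23), and MT-CO1, also for a cytochrome c oxidase subunit, 1.34-fold lower (1.32 to 1.36). The 24 mitochondrial ribosomal and transfer RNAs had a median 0.58 above that of all features (percentile 100), with 11 members at least 2-fold higher and 2 at least 2-fold lower. Their extremes were MT-TH at 8.22-fold higher (7.47 to 9.05), MT-TS2 at 8.22-fold higher (7.17 to 9.43), MT-TD at 3.84-fold lower (3.10 to 4.80) and MT-RNR2, the large rRNA, at 2.08-fold lower (2.08 to 2.09). The transfer RNA genes are short and adjoin the mRNA genes, so reads of neighbouring transcripts can be counted in them. For the 24 ribosomal and transfer RNAs, the matched lists had a median log2 ratio of -0.23, and the same limit of matching applies.

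**Figure D2:**
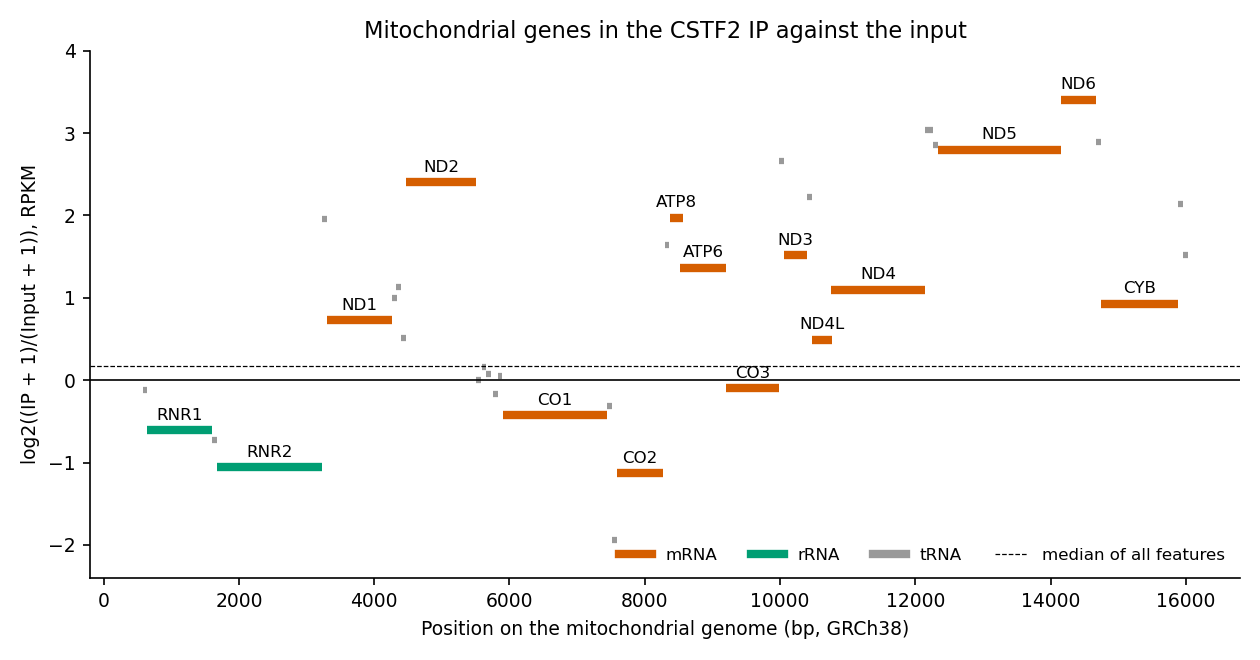
Each bar spans a mitochondrial gene on the x axis (bp, GRCh38) at its log2((IP + 1)/(Input + 1)) of RPKM on the y axis, coloured by mRNA, rRNA or tRNA, with the dashed line at the median of all features. The region from MT-TH to MT-TE, which holds MT-ND5 and MT-ND6, lies highest, and the rRNAs, MT-CO1, MT-CO2 and MT-CO3 lie below 0.

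Among the other lists, 2 stood apart as higher in the IP. The 22 cleavage and polyadenylation factors, the machinery CSTF2 belongs to, had a median 0.43 above that of all features (percentile 99.62), with 3 members at least 2-fold higher and none lower by that much. Besides CSTF2, SYMPK was 10.4-fold higher (8.52 to 12.8). It encodes symplekin, a scaffold protein that binds CSTF2. NUDT21 was 2.18-fold lower (1.59 to 3.06) and PAPOLA, the poly(A) polymerase gene, 1.30-fold lower (1.07 to 1.59), both less than 2-fold on the pseudocount scale. The list no longer stood apart without CSTF2 (percentile 98.55), although its median log2 ratio was 0.55 then and 0.60 with CSTF2. With CSTF2 kept in, it did not stand apart with a pseudocount of 5 RPKM (98.09) or a filter of 5 RPKM (98.54). Its median log2 ratio was 0.27 with that pseudocount and 0.75 with that filter, which left 8 members. The 8 nuclear-retained long noncoding RNAs had a median 1.02 above that of all features (percentile 99.96), with 5 at least 2-fold higher. MALAT1, of the nuclear speckles, had 492 RPKM in the IP and 85.8 RPKM in the Input, 5.73-fold higher (5.57 to 5.90). KCNQ1OT1 was 18.2-fold higher (15.0 to 22.3), whereas FIRRE at 1.01-fold (0.763 to 1.33) and JPX at 1.13-fold (0.737 to 1.69) had intervals that include 1.

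The lists of mRNAs that stood apart as lower were those of ribosomal proteins, histones and the respiratory chain. Of 78 cytosolic ribosomal protein genes, 34 were at least 2-fold lower and none at least 2-fold higher, with a median 1.10 below that of all features (-1.10, percentile 0). RPS12 had 66.0 RPKM in the IP against 417 RPKM in the Input, 6.32-fold lower (5.40 to 7.44), and RPS3A was 4.70-fold lower (4.01 to 5.53). FAU was 1.36-fold higher (1.21 to 1.53) and RPL3 1.27-fold higher (1.17 to 1.39). Of 55 replication-dependent histone genes, whose mRNAs end in a stem-loop in place of a poly(A) tail, 28 were at least 2-fold lower and 1 at least 2-fold higher (median -1.22 against all features, percentile 0). HIST1H4L was 7.06-fold lower (3.34 to 17.9) and HIST1H4C 5.71-fold lower (3.71 to 9.22). HIST1H4A had 0 reads in the IP and 22 in the Input. The 1 higher member, HIST2H2AA3, rested on 6 and 4 reads. HIST1H4K had a ratio of 0.985 (0.232 to 3.25). Histone genes are near-identical copies, so their reads can be shared. Of 63 nuclear-encoded respiratory chain genes, 22 were at least 2-fold lower and none at least 2-fold higher (median -0.89 against all features, percentile 0). COX6B1 was 6.71-fold lower (3.77 to 13.2) and COX7C 5.35-fold lower (4.59 to 6.26), with NDUFV1 at 1.85-fold higher (1.58 to 2.17) and NDUFB6 at 1.77 (0.931 to 3.29).

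Among features of at least 5 RPKM, leaving out small RNAs, pseudogenes and clone names, the lowest also included TIMM8B, for a chaperone of mitochondrial protein import, at 7.09-fold lower, CDKN3, for a cell cycle phosphatase, at 7.29-fold, OST4, for an oligosaccharyltransferase subunit, at 6.60-fold, and FAM96A at 8.15-fold. The lower ends of their counting intervals were 4.79, 4.35, 3.27 and 4.59. TTC28-AS1_2 and DLEU2_3 had 0 reads in the IP with 18 and 14 in the Input. TMEM107 on chromosome 17 (8173237 to 8176399) was 13.8-fold lower (7.85 to 27.0), with 12 IP reads and 491 Input reads. The snoRNA gene SNORD118 lies inside it on the same strand and was listed with 12 and 471 reads, so the value of TMEM107 cannot be separated from that snoRNA's.

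The list of the snRNA and 7SK type is mixed: besides spliceosomal snRNAs and 7SK it holds 7SL RNAs, vault RNAs, RMRP, RPPH1 and many pseudogenes of these. Of its 82 features, 61 were at least 2-fold lower and 4 at least 2-fold higher (median log2 ratio -3.17, -3.34 against all features, percentile 0). Many belong to multi-copy families whose reads can be split. Of the 82, 42 were at 0 in 1 library, and with those placed at a bound of 3 reads the median was -0.90. RNU6-4P had 0 reads in the IP and 474 in the Input, and RNU6-12P 0 and 48, while the higher extremes RN7SL751P and RN7SL444P each had 4 reads in the IP and 0 in the Input. The 56 snoRNA and scaRNA features went both ways, with 17 at least 2-fold higher and 17 at least 2-fold lower, and a median of -0.47 against all features (percentile 0.11). This call was lost with a filter of 5 RPKM, where the percentile was 89.98 and the median log2 ratio 0.23, and among lists matched on gene length too (percentile 5.06). SNORD97 and SNORD3D had 0 reads in the IP with 23 and 35 in the Input, and SNORD11B and SNORA71A had 4 and 5 reads in the IP with 0 in the Input.

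**Figure D3:**
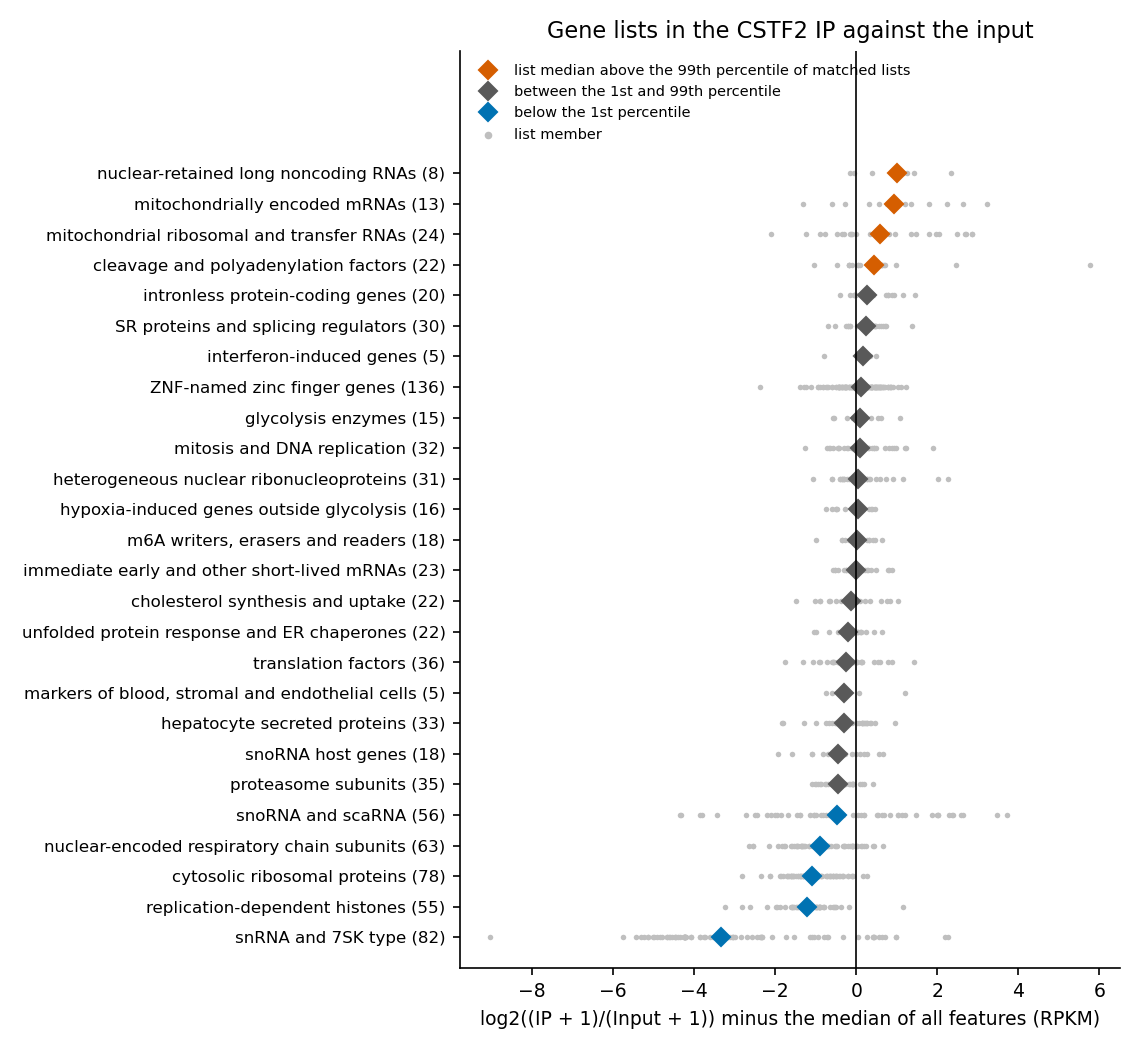
Each row is a gene list with its number of members past the filter, grey points are members and the diamond is the list median, on a log2((IP + 1)/(Input + 1)) scale of RPKM minus the median of all features. The 4 lists above percentile 99 and the 5 lists below percentile 1 of matched lists are coloured, and 42 of the 82 members of the snRNA and 7SK type are at 0 in 1 library, so their position depends on the pseudocount.

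PGK1, a glycolytic enzyme gene on chromosome X, had 12.5 RPKM in the IP and 4.70 RPKM in the Input, a ratio of 2.66 and a log2 ratio of 1.41 without a pseudocount. The authors' deposited table gives a log2 fold change of 1.38 for PGK1, which is a fold of 2.6. PGK1 was the only feature whose deposited values did not resolve into whole reads, so it has no counting interval. For every other feature the deposited fold change matched the recovered reads to within 2.36e-08 on the log2 scale. The 15 glycolysis genes as a list did not stand apart (median 0.10 against all features, percentile 81.525), and PGK1 was their only member at least 2-fold higher. PFKL was 2.33-fold higher (1.72 to 3.14) by ratio, while GAPDH was 1.29-fold lower (1.22 to 1.37) and ENO3 1.33-fold lower (1.16 to 1.53).

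Lists tied to the liver origin and to regulation in this line stayed within the range of matched lists. Hepatocyte secreted proteins (33 genes, percentile 18.015) ran from FN1, for fibronectin, at 2.25-fold higher (2.15 to 2.36) and F5 at 1.64-fold to APOA2 at 3.17-fold lower (2.62 to 3.87) and APOC3, with 0 reads in the IP and 18 in the Input. In cholesterol synthesis and uptake (22 genes, percentile 34.05), SREBF2, for the master transcription factor of the pathway, was 2.62-fold higher (2.22 to 3.09), while CYP51A1 was 2.70-fold lower (2.17 to 3.39) and EBP 1.83-fold lower (1.56 to 2.15). The hypoxia genes outside glycolysis (16, percentile 57.06) had no member past 2-fold, with P4HA2 at 1.69-fold and VEGFA at 1.62-fold higher and PLOD2 at 1.64-fold and ERO1A at 1.61-fold lower. The same held for the m6A writers, erasers and readers (18, percentile 61.32), where ZC3H13 was 1.86-fold and IGF2BP1 1.64-fold higher and WTAP 1.98-fold and HNRNPC 1.14-fold lower. Unfolded protein response genes (22, percentile 36.80) lay between EDEM1 at 2.32-fold and HYOU1 at 1.55-fold higher and MANF at 1.94-fold and ATF4 at 1.77-fold lower. Interferon-induced genes (5, percentile 68.79) spanned IFI6 and IRF9 at 1.97-fold and 2.05-fold higher and ISG15 at 1.63-fold lower. Among short-lived mRNAs (23, percentile 50.675), JUN was 2.21-fold (1.82 to 2.68) and DUSP5 3.09-fold (1.65 to 5.81) higher, and CYR61 1.33-fold and SGK1 1.59-fold lower. The 5 measured markers of blood, stromal and endothelial cells (percentile 13.805) had 1 member past 2-fold on the pseudocount scale, CD68, on 22 and 12 reads. By ratio, COL1A2 was 1.32-fold higher, LUM 1.41-fold lower and LYZ 2.20-fold lower, the last less than 2-fold on the pseudocount scale.

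Lists of RNA processing and growth genes were also within that range. Translation factors (36, percentile 31.93) held EIF4G1 at 3.22-fold (2.95 to 3.51) and EIF3B at 2.21-fold higher (1.97 to 2.47), and TPT1 at 3.11-fold (2.83 to 3.41) and EEF1B2 at 2.22-fold lower (1.98 to 2.48). SR proteins and splicing regulators (30, percentile 98.64) were led by SRRM2 at 3.12-fold higher (2.88 to 3.38) and PNN at 1.90-fold, with SRSF1 1.28-fold and SRSF9 1.48-fold lower. Among lists matched on gene length too, the SR list was at percentile 68.925. Heterogeneous nuclear ribonucleoproteins (31, percentile 85.405) had 4 members past 2-fold, all higher, and the extremes at both ends were mainly pseudogenes. HNRNPA1P68 had 14 reads in the IP and 0 in the Input, HNRNPA1P7 14 and 2, and HNRNPA3P5 2 and 18, and the one gene among the extremes, HNRNPLL, was 1.73-fold lower (1.04 to 3.05). Mitosis and DNA replication genes (32, percentile 85.44) had 6 higher members and 1 lower, from MKI67 at 4.43-fold (4.17 to 4.71) and MCM2 at 2.85-fold (2.46 to 3.29) to KIF11 at 1.53-fold lower and CCNB2 at 2.71-fold lower (1.65 to 4.70). ZNF-named genes (136, percentile 84.63) ranged from ZNF417 at 4.89-fold and ZNF598 at 2.86-fold higher to ZNF124 at 3.35-fold and ZNF593 at 6.09-fold lower. Intronless genes (20, percentile 94.82) included PURA at 5.28-fold (4.15 to 6.75) and SOX12 at 2.83-fold higher, with JUNB at 1.01-fold higher and ARF6 at 1.20-fold lower. The 35 proteasome genes (percentile 1.82) had no member past 2-fold, from PSMD2 at 1.52-fold and PSMB5 at 1.30-fold higher to PSMA4 at 1.88-fold and PSMD8 at 1.92-fold lower. Of 18 snoRNA host genes (percentile 1.09), 2 were at least 2-fold lower, SNHG6 at 3.47-fold (2.89 to 4.20) and SNHG22 at 4.17-fold (2.12 to 9.36). GAS5 at 2.31-fold and SNHG17 at 2.14-fold were the highest, both less than 2-fold on the pseudocount scale.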

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

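Alternatives with 20 reads, counting intervals, length matching or a gene left out were chosen after the data were seen. The number of features at least 2-fold higher (976) became 1830 and 186 with pseudocounts of 0.1 and 5 RPKM, 327 with a filter of 5 RPKM, 2569 and 151 at 1.5-fold and 4-fold, and 632 with at least 20 reads. The number lower (675) became 1023, 295, 407, 1484, 149 and 596 in the same order of settings. It was 1148 after small RNAs, mitochondrial, pseudogene and clone-named features were left out and both libraries rescaled to the rest (10950 features past the filter), and 284 by counting interval. The correlation across genes (0.847) was 0.751 and 0.894 with pseudocounts of 0.1 and 5 RPKM, 0.887 with no filter and 0.796 with a filter of 5 RPKM. The cleavage and polyadenylation list came to percentile 98.09 with a pseudocount of 5 RPKM, 98.54 with a filter of 5 RPKM and 98.55 without CSTF2, where its median log2 ratio was 0.55 against 0.60 with CSTF2. The snoRNA and scaRNA list came to percentile 89.98 with a filter of 5 RPKM, where its median log2 ratio turned from -0.30 to 0.23, and to 5.06 among lists matched on gene length too. Lists that newly stood apart were snoRNA host genes at percentile 0.83 with a pseudocount of 5 RPKM and 0.80 under that rescaling, SR proteins at 99.01 with a pseudocount of 5 RPKM, mitosis at 99.24 with a filter of 5 RPKM, and intronless genes at 99.79 with length matching. The cause was not tested in any of these cases, beyond the construction of the filters and thresholds. The other 193 list percentiles kept their side of the bounds, as the ribosomal protein, histone and respiratory chain lists did in each setting run. Some of the 193 still moved far. With length matching, SR proteins went from percentile 98.64 to 68.925 and translation factors from 31.93 to 2.88. Of the list medians, 141 moved by no more than the reach of their own interval to either side of its middle. Another 38 moved by more, and 1, that of the snoRNA and scaRNA list, reversed among the lists that stood apart. For the genes named, 399 values moved by no more than that reach of their counting interval on the log2 scale. The other 174 were counted as moved. They include PGK1 and features at 0 in 1 library, which have no finite interval to compare with. No named gene past 2-fold changed direction. Named genes were not recomputed under the filters, which do not change their value. Scaling moved the median of all features from 0.17 to 0 by construction, and a pseudocount of 5 RPKM moved it to 0.09. Depth limits the low features most, since 1 read is 0.311 CPM in the IP and 0.105 in the Input.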

Other observations

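The tests of CSTF2T reads, of capture through the nascent protein, of mitochondrial DNA and of counting error in the mitochondrial genes, and the gene groups and single genes named in this paragraph and the next, were chosen after the values were seen. A group of spectrin and plakin family genes was also picked by hand, and all 8 of its members past the filter were at least 2-fold higher. Their median was 1.81 above that of all features and their median exon length 16608.5 bp. SPTBN1 was 6.06-fold higher (5.86 to 6.28), PLEC 6.99-fold (6.04 to 8.11), SPTAN1 5.59-fold (5.14 to 6.08) and DSP, for desmoplakin, 4.39-fold. Of 8 centrosome and kinesin genes picked by hand, 5 were at least 2-fold higher, KIF15 among them at 6.02-fold (4.99 to 7.28). The group left out other kinesins, such as KIF11, which was lower in the IP, so this count depends on the choice of members. Of 13 RNA polymerase II subunit genes, 2 were at least 2-fold higher and 5 at least 2-fold lower. POLR2A, for the largest subunit, had the highest log2 ratio, at 5.90-fold higher (5.30 to 6.57), and POLR2K the lowest. The 78 mitochondrial ribosomal protein genes had a median of -0.52 against all features, with 9 at least 2-fold lower and 1 at least 2-fold higher. DEGS1, for a ceramide synthesis enzyme, was 9.33-fold higher (6.21 to 14.4) with only 2515 bp of exon.

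The Y RNA RNY1, which is in none of the fixed lists, had 0 reads in the IP and 393 in the Input. Of 21 features named as 5S rRNA pseudogenes, 20 were at least 2-fold lower (median -3.89 against all features). Their median length was 118 bp and reads can be shared among such copies, so they are not separate observations. The value of any at 0 in the IP depends on the pseudocount. Within the snRNA and 7SK type list already described, RPPH1, the RNA of RNase P, had 105 reads in the IP and 6920 in the Input, and RMRP 24 and 1190. Among 129 processed pseudogenes, 61 were at least 2-fold higher and 11 at least 2-fold lower, where reads can be shared with the parent genes. NEAT1 was 3.62-fold higher (3.16 to 4.16) and LINC-PINT 8.33-fold (4.08 to 18.4).

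The low ratios of ribosomal protein, histone and respiratory chain mRNAs could come from a loss of short transcripts. Across 7757 nuclear protein-coding genes the log2 ratio rose with gene length (Spearman 0.39 across genes), from a median of -0.73 in 133 genes of up to 1 kb to 0.46 in 1466 genes of over 8 kb. Genes of the 3 lists were not left out of this trend, and the 55 histone genes had a median length of 488 bp. The trend is thus in part the same pattern, and it was not computed without the 3 lists. Among random lists matched on both mean expression and gene length, however, the highest percentile of the 3 lists was still 0. This argues against the exon-union length as the whole cause. That length can exceed the length of the mRNA (its median was 2942 bp for the ribosomal protein genes). The matched lists also drew on all kinds of features. A loss of short mRNAs therefore stays open. The GC content of the longest protein-coding transcript also rose with the ratio (Spearman 0.27 over 7584 genes), and the cause was not tested. The density of GU-rich 6-mers in the mature transcript is a candidate explanation for the order of mRNAs, because CSTF2 binds GU-rich RNA. It did not go with a higher ratio (Spearman -0.087 over 7584 genes after removal of gene and transcript length, mean expression and GC content). That test leaves out the GU-rich element downstream of cleavage sites, which mature mRNAs lack, and capture that any antibody or bead would give stays open with 0 mock immunoprecipitation libraries used here.

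CSTF2's own mRNA was 69.9-fold higher in the IP. Reads of the paralog CSTF2T are an unlikely source, since CSTF2T had 63 reads in the IP and its ratio was 1.90, at most 2.63 by its interval. Genomic DNA of the locus is not a likely source either, since the 10 listed features within 1 Mb had a median ratio of 0.772 and reached at most 2.11 (CENPI). Capture of CSTF2 mRNA through the protein being made on it, or an introduced CSTF2 sequence, stays open, because it needs read profiles along the gene, of which 0 were used here. The 10.4-fold ratio of SYMPK, whose protein binds CSTF2, may be a further case of the former, and was not tested. SYMPK was picked out by its high ratio. Only 3 of the 22 cleavage and polyadenylation factors were at least 2-fold higher, CSTF2 and SYMPK among them. SYMPK also has 10628 bp of exon, and ratios ran higher in long genes.

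MT-ND6, MT-ND5 and MT-ND2 had the highest ratios of IP to Input among the mitochondrial mRNAs. A uniform floor of mitochondrial DNA is not a likely source of that order, because the mRNA with the lowest IP level of the 13, MT-ND3 at 3632 RPKM, sets a floor that could make up at most 11.7% of any of the 3. Counting error cannot span the gap either, since the lower end of the MT-ND6 interval was 22.6 times the upper end of the MT-CO2 interval. Without strand, antisense RNA opposite MT-ND6 and MT-ND6 mRNA cannot be separated in these values. No biological explanation was tested, and CSTF2-specific and unspecific capture stay open for all mitochondrial RNA.

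PGK1 is the only feature of the table whose deposited fold change has a single decimal (2.6, within a relative error of 1e-07), and the only one whose deposited columns do not resolve into whole reads. The cause was not tested.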
